A study of Rattus norvegicus with 4 samples.

How the data were processed

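Total RNA from 4 cultures of Rat-1·RasValA1 cells was hybridised to 4 single-colour oligonucleotide arrays, 1 per culture condition. Per the labels' protocols, amino allyl RNA was amplified from total RNA, coupled to Cy5 and fragmented by a procedure from Toray. Per the file headers, each array was read in a single channel at 3 gains that were related by least squares; scanner software and version are not given in the sources used here. The deposited scanner files give, for 27456 spots, a median spot intensity and a median local background intensity, neither of them scaled between arrays, and a mark of spot quality at each gain. Of these spots, 20174 carry a gene probe, each with its own Ensembl gene identifier, and 1344 are blank.

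The authors' deposited table holds a normalized intensity on a linear scale. Each of its columns was an exact straight line of that array's scanner signal (largest residual 5e-06), reaching 0 at the mean of the blank spots once the lowest and highest 5 percent were left out. Its median over the listed probes was 25 on every array, so each array was scaled by its own factor, and values were not centred per gene. Probes at or below the blank mean plus 2 SD, or marked as poor spots, are empty there. These steps were found from the values, since the labels do not describe them; the limit rebuilt here differed from the table's listing for 2 to 5 probes per array.

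Starting from the scanner files, the background was corrected with limma's normexp (offset 50) on the spot and local background intensities over all spots, control spots were then left out, log2 values were taken and the arrays were quantile normalized. This setting, the tests, the gene lists and the rule for named probes were fixed before the data were examined. The 8 gene probes marked as poor at any gain on any array were left out, which left 20166. A probe counted as detected where its signal exceeded the blank mean plus 2 SD (after leaving out 5 percent at each end). For each factor, probes detected on both arrays of at least 1 level entered, 13972 for IPTG and 13667 for zinc; for the difference of effects, probes detected on at least 2 arrays entered (14254).

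The local background proved to rise with the spot signal. Across gene probes its log2 value correlated with the log2 signal at r = 0.94 to 0.95 on each array. Among probes with a signal over 1000, the local background above that of the blank spots amounted to a median of 28.6% and 29.9% of the signal on the arrays without IPTG, and 38.6% and 36.6% on those with IPTG. A setting that subtracts the blank mean (floor 1), adds 50 and quantile normalizes was therefore added after the data were seen, and its values stand beside those with the local background.

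Each condition had 1 array, so a difference between 2 conditions has no replicate check and carries no p-value. For each factor, the layout gives 2 comparisons that share no array. An additive limma model (IPTG and zinc, lmFit and eBayes, two-sided, Benjamini-Hochberg threshold 0.05) used this, leaving 1 residual degree of freedom per probe. That residual contains the interaction as well as technical noise, so the test takes the interaction as error. Nothing in the labels says how many times the cultures were repeated. Counts of probes at least 2-fold apart in both comparisons of a factor are given with the count that independent lists of those sizes would share and with the count in opposite directions.

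The pipeline was tested on simulated data for the IPTG comparison (13972 probes, 5 draws, 100 probes changed 2-fold and 100 changed 4-fold in each). The constant variance prior called none of the changed probes. A prior with an intensity trend and robust fitting called 52.4% of the 2-fold and 85.0% of the 4-fold changes, with 20.2 false calls per draw on average. The criterion of 2-fold in both comparisons recovered 24.4% of the 2-fold and 99.0% of the 4-fold changes with 8.4 false probes.

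Alternatives were no background correction, offset 16, median scaling, the authors' table (probes listed on all 4 arrays, log2 without offset), no filter on dim probes, detection on all 4 arrays, the trend and robust prior, an adjusted p threshold of 0.10, fold limits of 1.5 and 3 and, for the difference of effects, a fold limit of 2. No table used here pairs the Ensembl identifiers with gene symbols (0 of 20174 matched). The 29 gene lists fixed beforehand, and the probes of Hras, the metallothioneins and Slc30a1, were therefore not analysed here, and results are given for probes by identifier. The rule for named probes took, for each factor and direction, the 10 probes with the largest value of the smaller of the 2 log2 differences, provided the sign was the same in both comparisons and the probe was detected on both arrays of the brighter level; for the difference of effects it took the 5 highest and 5 lowest. At most 2 identifiers per direction are printed for a comparison. The number of arrays limits precision. R 4.3.3 and limma 3.58.1 were used.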

Results

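Gene expression was measured in Rat-1·RasValA1 cells, a rat embryonic fibroblast line in which the activated Ras allele HrasG12V is under an IPTG-inducible promoter. HrasG12V encodes a form of the small GTPase Hras that stays in its active state. Cells in serum-free medium were kept for 24 h in 1 of 4 conditions: no addition, 5 mM IPTG, 3 µM ZnCl2, or 5 mM IPTG together with 3 µM ZnCl2. Each condition was measured on 1 array, so no condition had a replicate. The layout asks how IPTG, added to induce HrasG12V, changes expression, how zinc changes it, and whether each response depends on the other. No array held cells without this inducible allele, and the Hras probe was not identified. An effect of IPTG itself is therefore not separated from induction of HrasG12V, which was not measured here.

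Of the 20174 gene probes, 13830 (68.6%) were detected above the blank spots in cells without additions and 14606 (72.4%) with IPTG alone. Zinc alone gave 13449 (66.7%) and IPTG with zinc 14051 (69.6%). A single gene or control spot was saturated, on the array with IPTG alone. Repeat spots of the positive control sequences give the within-array error for bright spots. The SD of log2 signal over 24 spots of the first positive control was 0.16, 0.09, 0.07 and 0.13 on the arrays without additions, with IPTG, with zinc and with both. For the second positive control it was larger, at 0.22, 0.16, 0.17 and 0.19 on the same arrays.

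IPTG was followed by large differences that recurred in the separate pairs of arrays without and with zinc. In the first pair, 603 of 13972 probes were at least 2-fold higher with IPTG and 685 at least 2-fold lower. In the pair with zinc, 461 were higher and 540 lower. In both pairs, 229 probes were at least 2-fold higher, against 19.9 if the lists were independent, and 259 were at least 2-fold lower, against 26.5. Only 11 were 2-fold apart in opposite directions, against 45.9 for independent lists. Across probes, which are not independent replicates, the log2 differences of the 2 pairs correlated at r = 0.62 (Spearman's rho = 0.51).

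With the mean of the blank spots as background, 192 probes were at least 2-fold higher with IPTG in both pairs (10.8 for independent lists), 194 were lower (12.9), and 1 went in opposite directions. The lists from the local background (488 probes) and from the blank spots (386) shared 211 probes. A technical shift shared by both IPTG arrays would also recur in both pairs, and the counts for independent lists do not allow for it. Among bright probes, the local background was a larger share of the signal on both IPTG arrays (38.6% and 36.6%) than on those without (28.6% and 29.9%). How far this shaped the list of 488 was not tested. Many probes also crossed the detection limit with IPTG. On both IPTG arrays but neither of the others, 361 probes were detected, and 104 were detected on both arrays without IPTG but neither with it. For comparison, grouping the arrays across both factors (IPTG alone and zinc alone against the other pair) gave 63 and 59. Spots carrying no probe exceeded the limit in 16.8% of cases without additions, 17.9% with IPTG alone, 16.6% with zinc alone and 24.0% with both. A clear rise was thus seen only on the array with both. Blank spots exceeded it slightly more often with IPTG (7.51% alone, 7.59% with zinc) than without (6.25% without additions, 6.85% with zinc alone). The detection counts for IPTG therefore do not separate a difference in expression from a difference in limits.

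The probe with the largest recurring increase was ENSRNOG00000032832. Its normalized signal was 96.0-fold higher with IPTG without zinc and 125-fold higher with zinc, an average log2 difference of 6.78 ± 0.14 (SE of the additive model over 2 pairs). The blank-spot background gave 153-fold and 311-fold, and an offset of 16 in place of 50, which shrinks dim signals less, gave an average log2 difference of 7.87. In the authors' table its normalized intensity was 5.22 without additions and 5501 with IPTG, and 3.05 with zinc and 8678 with both. ENSRNOG00000032626 was 32.6-fold higher without zinc and 35.9-fold higher with it, or 34.3-fold and 53.3-fold with the blank spots. Among probes with lower signal, ENSRNOG00000015849 was 13.7-fold lower with IPTG without zinc and 10.2-fold lower with zinc. The blank-spot background gave 14.0-fold and 12.0-fold. ENSRNOG00000016064 ranked first among the lower probes at 19.5-fold and 14.1-fold, but with the blank spots as background it was only 1.48-fold and 3.77-fold lower. The 10 highest named probes were at least 6.56-fold higher in both pairs, and all 10 were also at least 2-fold higher in both with the blank spots as background. The 10 lowest were at least 5.29-fold lower, and 7 of them met the 2-fold limit with the blank spots.

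No single probe passed the additive limma test with its constant prior at an adjusted p of 0.05. The smallest adjusted p was 0.145, and 2827 probes (20.2%) had an unadjusted p under 0.05. In simulated data with 100 probes changed 2-fold and 100 changed 4-fold, this test also found no changed probe. An absence of calls can therefore go with real changes. More probes may have changed here, and the power of the test in that case was not simulated. With the intensity trend and robust prior, limma called 438 probes higher and 652 lower with IPTG. All 20 named probes were among them, but these had been chosen for large differences of the same sign on the same arrays. In simulated data this prior gave 20.2 false calls on average, beside 52.4% of 100 probes changed 2-fold and 85.0% of 100 changed 4-fold. The simulation changed far fewer probes than were called here, so that count gives no error rate for these calls. The direction of the excess turned with median scaling, where the same prior called 1902 probes higher and 674 lower. In the authors' table, scaled by the median of the listed probes, 2351 probes were at least 2-fold higher and 997 lower with IPTG without zinc, 1718 were higher and 600 lower with zinc, and the limma test called 588 higher and 246 lower. The median log2 IPTG difference there was 0.34 without zinc and 0.29 with zinc, against 0.00 and 0.01 after quantile normalization; median scaling gave 0.13 and 0.10.

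**Figure D1:**
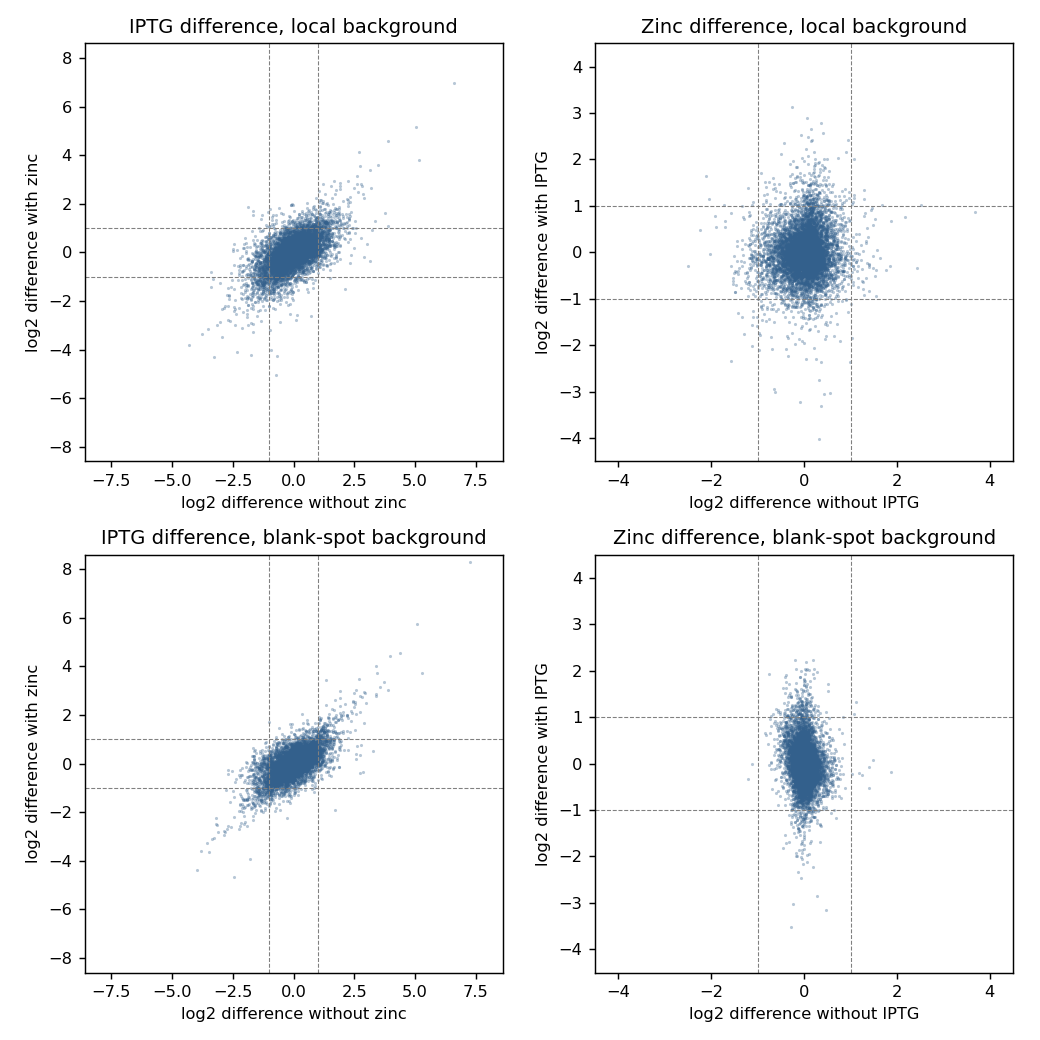
Log2 differences of probes detected on at least 2 arrays; the left panels set the IPTG difference with zinc (vertical axis) against that without zinc (horizontal axis), the right panels the zinc difference with IPTG against that without IPTG, for the local background (top) and the blank-spot background (bottom). Each point is 1 probe and dashed lines mark 2-fold; the IPTG differences lie along the diagonal (r = 0.62 and 0.67), while zinc differences without IPTG are narrow with the blank spots as background, with 11 probes beyond 2-fold.

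Zinc was followed by few differences that recurred between the pair without IPTG and the pair with IPTG. At least 2-fold higher with zinc in both pairs were 9 of 13667 probes (1.82 for independent lists), 10 were lower (2.14), and 7 went in opposite directions (4.51). This split depended on scaling: median scaling gave 4 higher and 15 lower, and the authors' table gave 1 higher (1.41 for independent lists), 24 lower (15.8) and 14 in opposite directions. The blank-spot background left 2 probes higher in both pairs, 0 were lower and 0 went in opposite directions. These 2 also belonged to the 9, and they are named here after their values were seen. ENSRNOG00000028841 was 3.19-fold higher with zinc without IPTG and 2.03-fold higher with IPTG, or 2.12-fold and 2.10-fold with the blank spots. In the authors' table its normalized intensity was 1066 without additions, 1946 with zinc, 482 with IPTG and 888 with both. ENSRNOG00000036954 was 2.09-fold higher without IPTG and 4.00-fold higher with IPTG, or 2.15-fold and 2.52-fold with the blank spots. Its spot on the arrays lay beside a patch where the array without additions differed from the 3 others, so its value on that array is less certain.

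The 2 zinc differences were of unequal size and barely related. Without IPTG, 78 probes were at least 2-fold higher and 143 lower with zinc. With IPTG, 319 were higher and 205 lower. The blank-spot background gave 9 and 2 without IPTG, and 239 and 134 with IPTG. The correlation across probes was 0.09 with the local background (rho = 0.07) and -0.14 with the blank spots (rho = -0.13). In the authors' table the split with IPTG turned to 546 higher and 1144 lower, and without IPTG it was 33 higher and 176 lower; median scaling gave 52 and 188 without IPTG. The median log2 zinc difference in that table was -0.20 without IPTG and -0.24 with it.

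The limma test called 0 probes for zinc with either prior. Its smallest adjusted p was 0.777 with the constant prior, and 856 probes (6.26%) had an unadjusted p under 0.05, against 880 with the trend and robust prior. With the blank spots as background these counts were 195 (1.43%) and 368. In the authors' table the constant prior gave 496 (3.88%). Of the 10 highest named probes for zinc, 2 were at least 2-fold higher in both pairs with the blank spots as background, and of the 10 lowest, 0 were at least 2-fold lower.

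**Figure D2:**
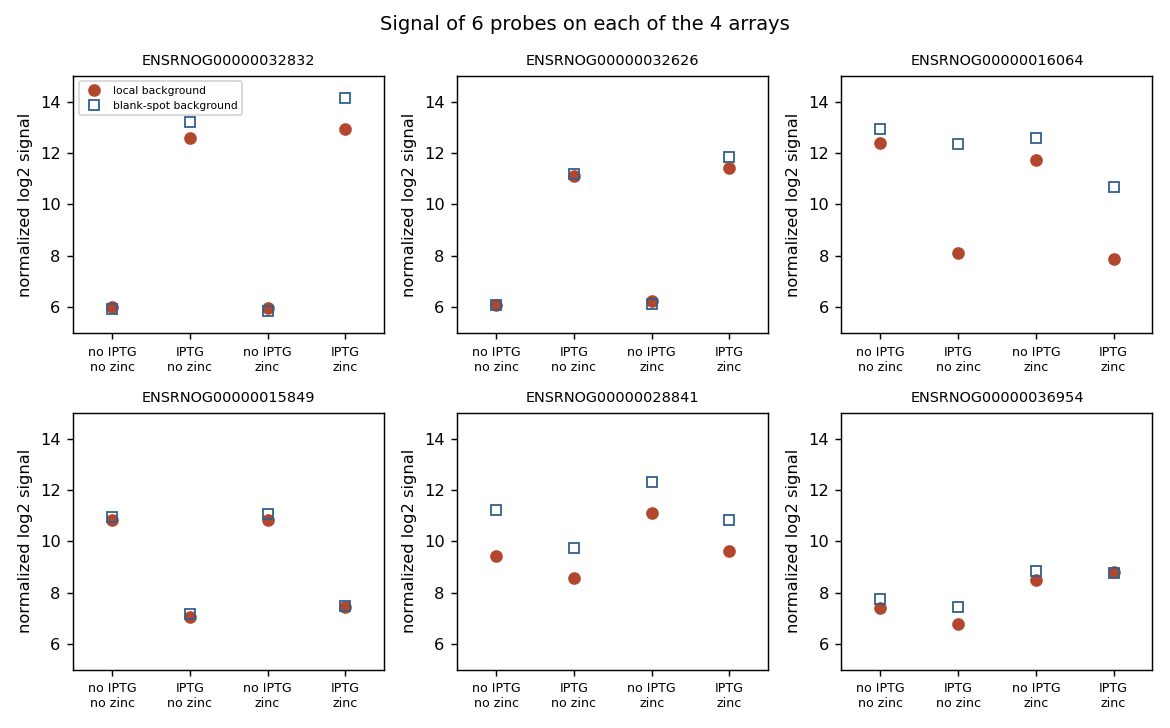
Normalized log2 signal (vertical axis) of 6 probes on each of the 4 arrays (horizontal axis), 1 array per condition, with the local background (filled circles) and the blank-spot background (open squares). The upper row and the first lower panel follow the IPTG arrays, of which ENSRNOG00000016064 does so mainly with the local background; ENSRNOG00000028841 and ENSRNOG00000036954 are higher on each zinc array than on the array with the same IPTG level without zinc.

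The dependence of one response on the other was measured as the IPTG difference with zinc minus that without zinc. For 45 of 14254 probes this was at least 4-fold above 0 and for 32 at least 4-fold below. The blank-spot background gave 13 and 14. The design leaves no degree of freedom to test a single probe. The 5 highest named probes ranged from 2.78 to 3.76 on the log2 scale and the 5 lowest from -4.35 to -3.35, but with the blank spots as background the same probes ranged from 0.36 to 1.64 and from -3.61 to 0.83. Of the 5 lowest, 2 kept nearly their size, at -3.65 and -3.48 with the local background and -3.61 and -3.13 with the blank spots, while the other 3 went to -0.04, 0.52 and 0.83.

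Whether the IPTG difference was smaller with zinc depended on the measure. At least 2-fold apart by IPTG without zinc but under 1.5-fold apart with zinc were 471 probes, while 260 were at least 2-fold apart with zinc but under 1.5-fold apart without it. The blank-spot background gave 416 and 114. The slope of the difference of effects on the average IPTG difference, in which equal array noise cancels, was -0.12 (95% bootstrap interval over probes -0.14 to -0.09). This corresponds to IPTG differences with zinc of 0.89 times those without. With the blank spots the slope was -0.19 (-0.22 to -0.17) and the ratio 0.82. Probes are not independent, so these intervals do not cover differences between cultures or arrays. Among the 488 probes at least 2-fold apart by IPTG in both pairs, the difference was smaller with zinc for 273 (55.9%), and for 204 of 386 (52.8%) with the blank spots. Of the 10 highest named probes, 8 had a larger IPTG difference with zinc, and 6 did with the blank spots; of the 10 lowest, 4 and 3 did.

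For the probes at least 2-fold apart by zinc in the IPTG cells, the sign of the IPTG difference was counted. With the blank spots as background, 203 of the 239 probes at least 2-fold higher with zinc (84.9%) had a lower average signal with IPTG, and 94 of the 134 at least 2-fold lower (70.1%) had a higher one. Among the 239, the median log2 IPTG difference was -1.15 without zinc and 0.20 with zinc, and the median zinc difference without IPTG was -0.05. Among the 134 these medians were 1.05, -0.26 and -0.02. With the local background, 229 of 319 (71.8%) and 105 of 205 (51.2%) had an average IPTG difference of the opposite sign. Both arrays that selected these probes also enter their IPTG differences, so a deviation of the array with IPTG alone would give such shares by selection, and they are no test of a zinc effect.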

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

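Chosen after the results were seen were the tests of the local background on the contrast between zinc differences, of dim probes with the blank-spot background, of arrays per group and of neighbouring probes among the zinc differences without IPTG. The test of neighbouring probes among the zinc differences with IPTG was set beforehand. Its blank-spot background, however, was added after the data were seen.

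At least 2-fold apart by IPTG in opposite directions without and with zinc were 11 probes, and 7 probes were so for zinc without and with IPTG; the difference was not tested, and with the blank spots as background the counts were 1 and 0. Spots listed as carrying no probe entered none of the IPTG or zinc differences. They exceeded the limit set by the blank spots in 16.8% of 5273 cases without additions, 17.9% with IPTG, 16.6% with zinc and 24.0% with both. Among the blank spots themselves this was 6.25% to 7.59%. Spots listed as quality-control probes exceeded it in 63.5% of 521 cases without additions, 69.1% with IPTG, 61.0% with zinc and 63.7% with both.

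The zinc difference was wider with IPTG than without (524 against 221 probes at least 2-fold apart). The local background does not account for the contrast itself, since the ratio of the counts went from 2.37 to 33.9 with the blank spots as background. That ratio rests on only 11 probes without IPTG. The list with IPTG did depend on the background: its count fell from 524 to 373, and the 2 lists shared 204 probes. Position on the array leaves most of it: after the median of each of 192 stretches of spots was subtracted, 90.1% of the count with IPTG was left, and 33.2% of the 373 probes found with the blank spots had another within 2 spots, against 24.1% to 36.5% in random draws, although with the local background this was 47.7% of the 524, above the 34.3% to 44.8% of random draws. Noise of dim probes was first tested with the local background, where the spread in the brightest 25% of probes was 1.18 times as wide with IPTG (bootstrap interval 1.09 to 1.249), which left it undecided; the test was then repeated with the blank spots, where it was 2.26 times as wide (2.14 to 2.39), so dim probes are excluded as the whole source only for that background. The array with IPTG and zinc stood apart from the others in its blank mean and median gene signal. On the arrays without additions, with IPTG, with zinc and with both, the blank means were 66.0, 66.0, 66.5 and 69.8. The median gene signals were 77.6, 78.1, 77.9 and 82.8. Of spots carrying no probe, 24.0% exceeded the limit with both, against 16.6% to 17.9% otherwise. Whether this bears on the zinc difference was not tested. With 1 array per group, a dependence of the zinc response on IPTG cannot be told apart from a single IPTG culture or array that stands apart.

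By its slope over all probes the IPTG difference was smaller with zinc, although among probes 2-fold apart in both pairs this held for only 55.9%. The quantile step is not needed for the slope, since median scaling gave a slope of -0.15 (-0.17 to -0.12). Median scaling only shifts each array on the log2 scale, which leaves a slope unchanged. Other differences in scale between arrays were not tested. An array without zinc that stands apart, either that with IPTG alone or that without additions, would give the same sign. With 1 array per group this cannot be told apart from an effect of zinc on the response to IPTG.

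The zinc differences without IPTG largely track 2 technical sources. Over the 221 probes at least 2-fold apart with the local background, the difference ran against that of the local background (r = -0.75). That background is subtracted in this setting and the probes were selected on the result, so a negative r follows in part by construction. Without subtraction, the spot signal differed by under 1.5-fold for 86.0% of the 221, while the local background differed by over 1.5-fold for 64.7%. Of the 221 probes, 9 were also among the 11 found with the blank spots. Another such probe lay within 2 spots for 41.2%, against 12.2% to 26.2% in random draws. Of the 11 probes found with the blank spots, 7 (63.6%) had another within 2 spots, against 0% to 18.2% in random draws; these 7 lie in block 20, columns 54 to 58 and rows 3 to 7, and for 6 of them the array without additions stood apart from the 3 others. A blemish on that array may account for those 6. The biological part of the zinc response without IPTG stays open, and ENSRNOG00000028841 lies outside the patch.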

How the results depend on the processing

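The alternatives with the blank spots as background and with median scaling under the trend and robust prior were chosen after seeing the data; the others were planned. Median scaling, no filter on dim probes, detection on all 4 arrays and the adjusted p threshold of 0.10 kept the totals over both directions and the constant-prior calls within 1.5 times, but median scaling moved the probes 2-fold higher with zinc in both pairs from 9 to 4. Over all alternatives, 55 of the counts, limma calls and pair correlations stayed close, 40 moved and 3 reversed, all 3 of them the zinc pair correlation. The cause was not tested unless named. No background correction gave 537 probes at least 2-fold apart by IPTG with zinc, 10 by zinc without IPTG, 294 by zinc with IPTG, 2 by zinc in both pairs and 14 past the 4-fold limit for the difference of effects, with pair correlations of 0.67 for IPTG and -0.15 for zinc, the latter reversed. The blank spots gave 628, 11, 373, 2 and 27 for the same counts and correlations of 0.67 and -0.14, the latter again reversed. Offset 16, which shrinks dim probes less, gave 2036 and 1521 probes for IPTG without and with zinc, 772 in both pairs, 369 and 916 for zinc without and with IPTG, 46 in both pairs and 165 for the difference of effects. The authors' table, which has no offset, gave 3348, 2318 and 1278 for IPTG, 1690 for zinc with IPTG and 302 for the difference of effects, a zinc pair correlation of -0.082 (reversed), and 834 limma calls for IPTG. The trend and robust prior gave 1090 limma calls for IPTG with the local background 1344 with the blank spots and 2576 with median scaling, against 0 with the constant prior. By construction, a fold limit of 1.5 gave 3054, 2519 and 1397 for IPTG without zinc, with zinc and in both pairs and 1008, 1694 and 195 for zinc. A limit of 3 gave 352, 264 and 110 for IPTG and 19, 103 and 0 for zinc, and a limit of 2 for the difference of effects gave 835.

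For the first-ranked named probes, leaving out each array in turn leaves 1 pair without a test: the log2 differences were 6.59 to 6.96 and -4.29 to -3.82 for IPTG and 1.29 to 1.34 and -2.33 to -1.57 for zinc. The first-ranked probe higher with zinc had an average log2 difference of 1.32, which was -0.28 in the authors' table (reversed), 0.0017 with the blank spots and 0.0016 with no background correction. The first-ranked probe lower with zinc, at -1.95, likewise shrank to -0.38, -0.12 and -0.12. Leaving out an array likewise leaves 1 intact pair for the counts, 1288 or 1001 probes for IPTG and 221 or 524 for zinc, while the limma calls then have no residual degree of freedom. Averaging the probes of a gene was not run because each identifier has 1 probe, and the gene lists were not run because no symbols were paired. No paired analysis was possible because each group has 1 array, so no replicate numbers could pair arrays; the additive model already compares arrays within each level of the other factor. Signal over background limits dim probes: 4798 of 20166 probes were detected on no array.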

Other observations

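No test was run for the values that follow. The second positive control sequence, on 24 spots per array, had a median signal of 8399 without additions and 8762 with zinc, against 13028 with IPTG and 11760 with both, with an SD of log2 signal between spots of 0.16 to 0.22. The first positive control had 14828, 13389, 13909 and 14838 on the same arrays. What these sequences target is not given in the sources used here.

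Detection moved the other way for zinc than for IPTG. On both zinc arrays but neither of the others, 28 probes were detected, and 132 were detected on both arrays without zinc but neither with it. Grouping the arrays across both factors gave 63 and 59. The detection limit was higher on the zinc arrays, at 68.3 with zinc alone and 71.8 with both. It was 67.7 without additions and 67.6 with IPTG alone. These counts therefore do not separate a difference in expression from a difference in limits.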
